A study of Mus musculus with 6 samples.

How the data were processed

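The study measured messenger RNA by paired-end sequencing of granulosa cells from mouse ovaries, in 3 libraries labelled wild type and 3 labelled Jmjd3 knockout. Per the labels' protocols, total RNA was extracted from freshly isolated cells and libraries were made with the NEBNext Ultra RNA kit. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2 were used with the GRCm38 genome. The deposited values are whole-number counts per gene, not normalized, with 49315 genes in each file. The annotation release, the strand setting, the treatment of reads that match several places, and whether read pairs or single reads were counted are not given in the sources used here. Genes that share sequence with a copy, or that overlap another gene, therefore have uncertain values. The age of the mice is in the labels, but the stage of the oestrous cycle and any hormone treatment are not given in the sources used here.

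Gene identifiers were matched to GENCODE M21: 49056 matched and 259 did not, and 91.4% of the matched genes had the same start and end as in the count files. Coordinates are those of the count files, on GRCm38, counted from 1. Groups and replicate numbers were taken from the labels, and no sample was left out.

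The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (18250 kept, 17050 had no count in any library), and library sizes were scaled by TMM. The libraries labelled KO were compared with those labelled WT by the robust quasi-likelihood test, with genotype as the only term and Benjamini-Hochberg adjustment over all genes kept. A gene was called at an adjusted p under 0.05. CPM are edgeR's counts scaled to the TMM-adjusted library size. Values of log2 CPM used a prior count of 2, and 1 CPM corresponds to between 42.5 counts (KO replicate 2) and 51.4 counts (WT replicate 1). The common biological coefficient of variation was 0.136. Intervals come from the same fit at 95% confidence.

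The design, the tests, 26 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Kdm6b, Kdm6a, Ezh2 and 12 granulosa cell genes always. It also named the 10 called genes with the largest increase and the 10 with the largest decrease among those with a mean of at least 5 CPM and no overlap between groups, leaving out predicted genes and pseudogenes (9 qualified as decreased). Of each list it named the 4 members with the smallest p. Gm28438, the plotted genes Ptgs2, Tnfaip6 and Has2, and any other gene outside it were chosen after their values were seen. Lists were tested by camera of limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation as an alternative, and by fry. A few genes that the rule names are not reported here. List members that were filtered for low counts, or had no match to a symbol, were not tested; they include 16 of the 39 Hox genes.

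The steps were tested on simulated data before use. Counts for the 18250 genes were drawn from the means, library sizes and dispersions of these libraries for the comparison of KO against WT, with 200 genes changed. The test recovered 34.3% of the genes changed 1.5-fold (67 genes), 65.7% of those changed 2-fold (67 genes) and 92.4% of those changed 4-fold (66 genes), in the right direction, and 5.88% of its calls were unchanged genes. A list of 19 steroidogenesis genes raised 2-fold was called by camera, as was 1 other list, the luteal markers, which share members with it. Each gene was drawn independently, so the simulation does not show how camera behaves where list members vary together. In these libraries the estimated correlation was 0.09 for the steroidogenesis list and 0.68 for the oocyte list.

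The alternatives were other normalizations (RLE, upper quartile), DESeq2 1.42.0, limma-voom with quality weights, no filter and a filter at a mean of 1 CPM. Others were the replicate number as a block, leaving out each library in turn and a minimum absolute log2 fold change of 1.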

Results

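Granulosa cells, the somatic cells that surround and nourish the oocyte in ovarian follicles, were taken fresh from the ovaries of wild-type (WT) mice and of mice with a granulosa cell-specific knockout (KO) of Jmjd3. This gene, also named Kdm6b, encodes a demethylase that removes the repressive H3K27 methyl mark from histones. RNA was sequenced from 3 libraries labelled WT and 3 labelled KO, all labelled as C57BL/6J, to ask which genes change in granulosa cells without JMJD3. Gene counts per library summed to between 42379018 (KO replicate 2) and 49901493 (WT replicate 1), and between 26097 and 27057 genes had at least 1 count. The labels do not say that the replicates came from separate animals, so the p-values measure the spread between these libraries, which may be technical. Levels are normalised read counts (CPM) as mean ± SD with n = 3 per group. Differences are log2 fold changes, KO minus WT, with SE, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 18250 genes.

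Kdm6b RNA (chromosome 11, 69398508 to 69413675, GRCm38) was not lower in the libraries labelled KO. It stood at 72.8, 66.3 and 66.2 CPM in WT replicates 1 to 3 and at 64.7, 68.6 and 112 CPM in KO replicates 1 to 3. The group means were 68.4 ± 3.76 and 81.9 ± 26.5 CPM, a log2 fold change of 0.26 ± 0.22 (SE; 95% confidence interval -0.29 to 0.81; adjusted p = 0.755, edgeR). Without KO replicate 3 the log2 fold change was -0.04 (adjusted p = 0.875). The labels do not state which exons were removed, and counts over the whole gene can retain reads from the remaining exons. This value therefore does not decide whether the deletion took place, and the genotype of each group below rests on its label alone. The related demethylase gene Kdm6a (-0.08 ± 0.07 SE, adjusted p = 0.775) and the methyltransferase gene Ezh2 (-0.12 ± 0.08 SE, adjusted p = 0.695) did not pass the test in edgeR.

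In the libraries labelled KO, 23 genes were higher and 17 were lower at an adjusted p under 0.05. The largest increase among the called genes named for the size of their change was in Wdfy1, which encodes an endosomal FYVE domain protein: 8.88 ± 1.10 CPM in WT against 40.9 ± 2.63 CPM in KO (log2 fold change 2.20 ± 0.11 SE, adjusted p = 3.13e-05). The interferon-inducible gene Xaf1 rose from 5.13 ± 0.17 to 17.8 ± 2.76 CPM (1.79 ± 0.13 SE, adjusted p = 0.000487). Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, rose from 42.8 ± 0.88 to 119 ± 16.4 CPM (1.47 ± 0.10 SE, adjusted p = 0.000254). The melanosomal gene Oca2 rose by 1.51 on the log2 scale, Efcab7 by 1.04, Paqr9 by 0.99, Bpifb4 by 0.93 and the amino acid transporter gene Slc7a8 by 0.61 (adjusted p from 0.0125 to 0.0467). Serpina3g (1.19) and Dynlt1b (0.81) also rose, but both have close copies in the mouse genome that could share reads, so their values are uncertain.

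Among the genes that were lower was Amhr2, the receptor through which granulosa cells respond to anti-Müllerian hormone. It fell from 267 ± 26.6 to 133 ± 7.02 CPM (log2 fold change -1.01 ± 0.09 SE, 95% confidence interval -1.21 to -0.81, adjusted p = 0.00212). The transcription factor gene Wt1, a marker of immature granulosa cells, fell from 93.0 ± 6.99 to 64.0 ± 1.41 CPM (-0.54 ± 0.07 SE, adjusted p = 0.0246). Nr0b1, which encodes an orphan nuclear receptor that represses steroidogenic genes, fell from 22.8 ± 2.79 to 13.3 ± 0.87 CPM (-0.77 ± 0.11 SE, adjusted p = 0.026). The angiotensin II receptor gene Agtr2 had a log2 fold change of -0.92, the magnesium transporter gene Nipal1 of -0.77, the ubiquitin ligase gene Lnx1 of -0.56. The scavenger receptor gene Cd36 had one of -0.48 and the polarity gene Crb1 one of -1.31 (adjusted p from 0.00267 to 0.031 for the 5). The mitochondrial gene mt-Nd3 showed the largest decrease among the called genes with a mean of at least 5 CPM that were named for the size of their change, from 9.70 ± 1.84 to 0.31 ± 0.06 CPM (-4.97 ± 0.23 SE). It has a near-identical copy in the nuclear genome, Gm28438 on chromosome 1 (24612775 to 24613119), whose counts rose from 0.39 ± 0.17 to 11.4 ± 1.55 CPM, so the values of both are uncertain. The mitochondrial genes beside it were also called lower, at low levels: mt-Nd4l (1.38 ± 0.12 against 0.44 ± 0.04 CPM), mt-Tr (0.47 ± 0.14 against 0.03 ± 0.02 CPM) and mt-Tg (0.66 ± 0.02 CPM in WT and listed at 0 in KO). The value of mt-Nd4l is uncertain too, since its nuclear copy Gm10222 is identical over 294 aligned bases.

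**Figure D1:**
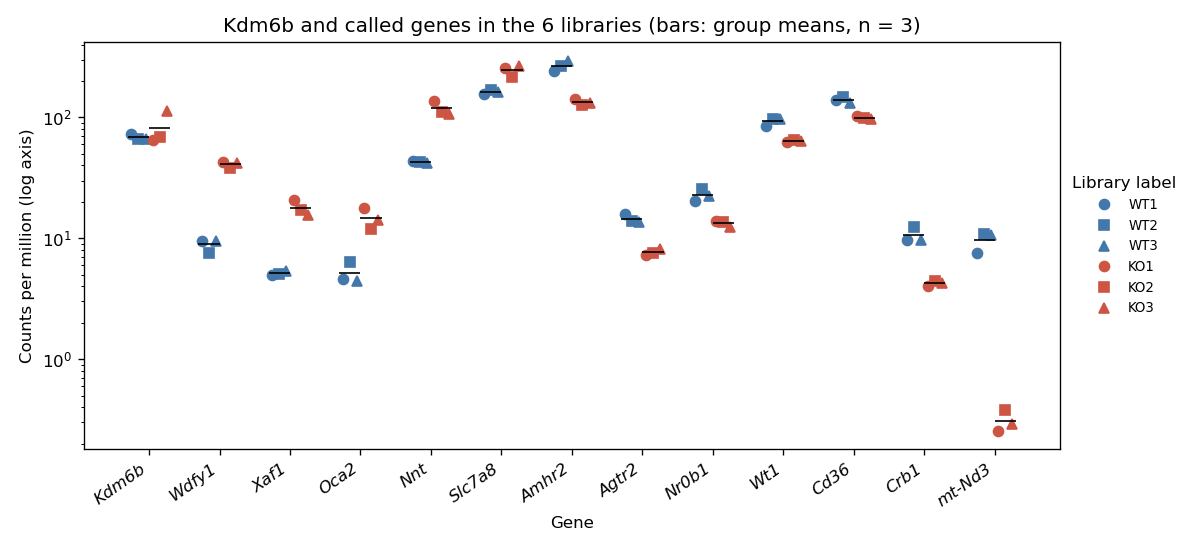
Normalised read counts (CPM) on a log axis for Kdm6b and 12 genes past the threshold in each library (blue, WT; red, KO; circles, squares and triangles are replicates 1, 2 and 3; black bars are group means, n = 3). Kdm6b overlaps between the groups, while the called genes do not, with Amhr2 at 267 CPM on average in WT and 133 CPM in KO.

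All 40 called genes separated the 3 KO libraries from the 3 WT libraries without overlap, as did 15.6% of all tested genes where chance gives 10%. Without WT replicate 1, 2 or 3 the test called 17, 8 or 9 genes in all, of which 15, 8 and 9 were among the 40. Without KO replicate 1 or 2 it called 26 or 36, of which 22 and 24 were among the 40. Leaving out KO replicate 3 raised the number to 421 (324 higher, 97 lower), with all 40 among them. Wdfy1, Xaf1, Nnt, Nipal1 and mt-Nd3 were among 8 genes that stayed past the threshold in each of these 6 fits. Staying called does not tell the loss of JMJD3 from strain background, a candidate explanation given below for Wdfy1, Nnt and mt-Nd3. The same limit holds for Xaf1, which lies within 5 Mb of Kdm6b. Amhr2 lost its call without WT replicate 2 (adjusted p = 0.0542, log2 fold change -1.02), and Crb1 without WT replicate 2 (0.0606) or 3 (0.0649). The other named genes lost theirs in at least 2 of the 6, with the highest adjusted p of each between 0.114 (Agtr2) and 0.317 (Paqr9) in edgeR (Wt1 0.218, Nr0b1 0.222), and kept their sign.

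Most marker genes of granulosa cells did not pass the test. Of the 22 granulosa cell markers, Amhr2 and Wt1 fell and the other 20 did not pass, and the count was the same when adjusted over the list alone. The median log2 fold change was 0.14 (adjusted p = 0.29 by camera). The follicle-stimulating hormone receptor gene Fshr stood at 123 ± 8.5 CPM in WT and 128 ± 16.5 CPM in KO (0.06 ± 0.10 SE). The transcription factor gene Foxl2 stood at 112 ± 8.56 and 123 ± 7.03 CPM, and Amh at 901 ± 169 and 827 ± 95.9 CPM. The estrogen receptor gene Esr2 stood at 187 ± 12.8 and 172 ± 14.3 CPM. The inhibin subunit genes Inha (0.31 ± 0.14 SE, adjusted p = 0.553) and Inhba (0.55 ± 0.30 SE, adjusted p = 0.635) did not pass in edgeR either, and Inhba reached 2202 CPM in KO replicate 3. Of 32 genes of TGF-beta, BMP and activin signalling, the BMP type I receptor gene Acvr1 rose from 43.0 ± 2.34 to 65.2 ± 6.67 CPM (0.60 ± 0.09 SE, adjusted p = 0.0343). It was also the only one adjusted over the list alone, and 31 did not pass. That list as a whole was higher (camera adjusted p = 0.0144; adjusted p = 0.577 with an estimated correlation), a call that ended without WT replicate 1 (0.119) or KO replicate 3 (0.116). Acvr1 itself lost its call in 4 of the 6 fits that left out a library, with adjusted p up to 0.258.

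Steroidogenic and luteal genes, in lists that share members, stood higher in the libraries labelled KO as groups, with no member past the threshold over all genes. In the luteal list KO replicate 3 lay within the range of the WT libraries. Of 19 steroidogenesis genes, 18 had a positive fold change with a median of 0.42, and 7 were higher when adjusted over the list alone (camera adjusted p = 2.92e-07; adjusted p = 0.544 with an estimated correlation). Star, which moves cholesterol into mitochondria, stood at 373 ± 28.5 CPM in WT and at 1165, 760 and 617 CPM in KO replicates 1 to 3 (1.18 ± 0.23 SE, adjusted p = 0.212). It passed without KO replicate 1 (0.0334) and without KO replicate 3 (0.0106). Por, the electron donor of cytochrome P450 enzymes, stood at 127 CPM in WT and 183 CPM in KO (0.52 ± 0.10 SE, adjusted p = 0.0922), and passed without KO replicate 3 (0.0101). Cyp11a1, the side-chain cleavage enzyme, stood at 3074 ± 158 and 4183 ± 1470 CPM, with KO replicate 3 at 2740 CPM (0.44 ± 0.24 SE, adjusted p = 0.619), and passed without that library (0.0136). Akr1c18, which inactivates progesterone, stood at 9.81, 12.9 and 5.75 CPM in WT and at 854, 454 and 67.6 CPM in KO (adjusted p = 0.346 in edgeR).

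Of 13 luteal cell markers, 11 had a positive fold change with a median of 0.44. Adjusted over the list alone, 3 were higher and 1 was lower (camera adjusted p = 0.000498; adjusted p = 0.577 with an estimated correlation). The prolactin receptor gene Prlr stood at 520 CPM in WT and 785 CPM in KO (0.59 ± 0.13 SE, adjusted p = 0.19). The luteinizing hormone receptor gene Lhcgr stood at 351 ± 40.2 and 541 ± 173 CPM (0.63 ± 0.23 SE, adjusted p = 0.486). The median of the luteal list against the WT mean was 0.87 in KO replicate 1, 0.57 in KO replicate 2 and 0.05 in KO replicate 3. WT replicate 1 stood at 0.12. The luteal list shares Star, Cyp11a1, Hsd3b1, Scarb1 and Akr1c18 with the steroidogenesis list, so their results are not separate. The steroidogenesis list also holds the theca cell gene Cyp17a1, although camera did not call the theca and interstitial cell list. Which cells gave the higher levels of these lists was not tested. Of 22 cholesterol biosynthesis genes, 21 had a positive fold change with a median of 0.26, but none passed over all genes or adjusted over the list alone. The list was higher by camera (adjusted p = 0.000101; adjusted p = 0.627 with an estimated correlation), a call that ended without KO replicate 1 (0.0655). Its medians in KO replicates 1 to 3 were 0.55, 0.12 and 0.04, with WT replicate 1 at 0.20. An example was Srebf2, the master regulator of sterol synthesis, at 0.29 ± 0.07 SE. The endothelium, immune cell and red blood cell lists had medians of 0.70, 0.54 and 1.96 in KO replicate 1, the library with the highest luteal and cholesterol medians.

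Ovulation genes were high as a group in 1 library, KO replicate 3, where the list median was 1.20 against -0.11 to 0.12 in the other libraries. Of the 20 tested members 16 had a positive fold change, so not every member was higher in the KO group. Areg and Ereg, the growth factors that relay the luteinizing hormone signal within the follicle, stood at 241 and 261 CPM there and at no more than 0.98 and 1.31 CPM in any other library. The progesterone receptor gene Pgr stood at 24.2 CPM there and at no more than 1.19 CPM elsewhere, and the aromatase gene Cyp19a1 at 1113 CPM against 190 to 319 CPM elsewhere. None of the 20 tested members of the ovulation and cumulus expansion list passed over all genes or adjusted over the list alone. The fold changes of Areg (7.45 ± 3.26 SE, adjusted p = 0.597), Pgr (3.40 ± 1.68 SE, adjusted p = 0.626) and Cyp19a1 (1.29 ± 0.70 SE, adjusted p = 0.646) did not exceed the spread between libraries. The list was higher by camera (adjusted p = 0.0448; adjusted p = 0.817 with an estimated correlation), but not without KO replicate 3 (0.817), WT replicate 1 (0.32) or WT replicate 3 (0.0746). None of the 25 immediate early and stress genes passed over all genes or adjusted over the list alone (median 0.26, camera adjusted p = 0.279), and Nr4a3 stood at 93.4 CPM in KO replicate 3 against at most 1.22 CPM elsewhere. This list was higher without KO replicate 1 (0.00917) or 2 (0.014) and lower without KO replicate 3 (0.0191; 0.491 with an estimated correlation).

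**Figure D2:**
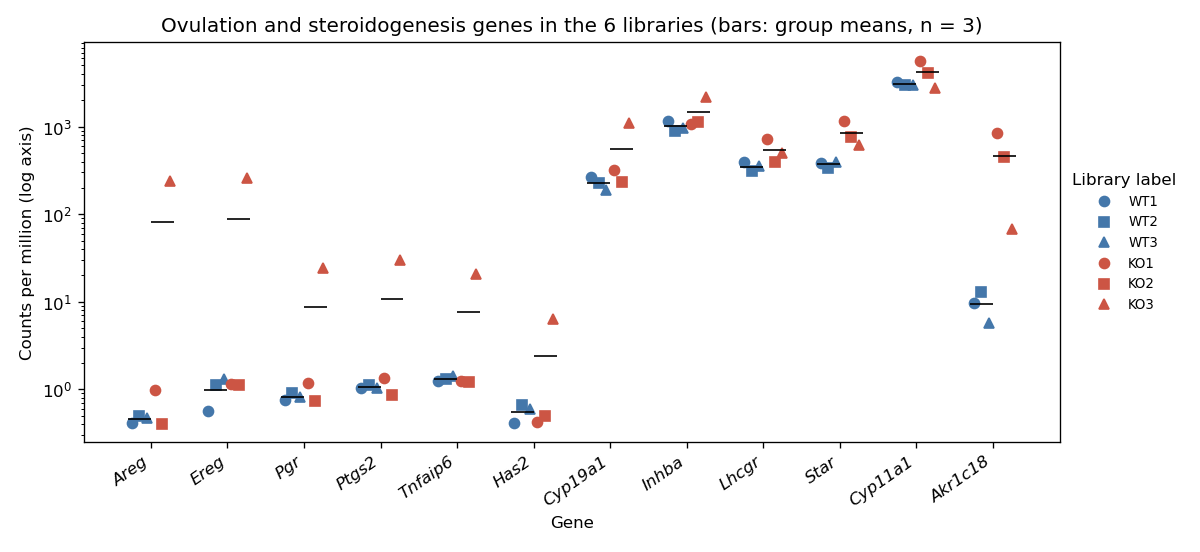
Normalised read counts (CPM) on a log axis for 12 genes of the ovulation, granulosa, steroidogenesis and luteal lists in each library (blue, WT; red, KO; circles, squares and triangles are replicates 1, 2 and 3; black bars are group means, n = 3). Areg, Ereg and Pgr are high in KO replicate 3 alone, while Star and Akr1c18 are higher in each KO library than in any WT library.

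Oocyte genes were lower as a group in the libraries labelled KO. Each of the 23 tested had a negative fold change, with a median of -0.31, and the medians in KO replicates 1 to 3 were -0.35, -0.37 and -0.17, with WT replicate 1 at -0.17. None passed over all genes, and 8 were lower when adjusted over the list alone (camera adjusted p = 5.00e-08; adjusted p = 0.577 with an estimated correlation). Gdf9, an oocyte-secreted growth factor, stood at 165 CPM in WT and 121 CPM in KO (-0.45 ± 0.12 SE, adjusted p = 0.283). The zona pellucida gene Zp2 stood at 126 and 95.6 CPM (-0.39 ± 0.11 SE, adjusted p = 0.312). Red blood cell genes were higher as a group, with all 7 tested at a positive fold change and a median of 1.25. The medians in KO replicates 1 to 3 were 1.96, 1.17 and 0.48, against -0.64, 0.20 and 0.42 in WT replicates 1 to 3. KO replicate 3 thus lay close to WT replicate 3. Slc4a1 passed over all genes at a low level (0.23 ± 0.10 against 1.01 ± 0.15 CPM, adjusted p = 0.0406). Adjusted over the list alone, 2 passed (camera adjusted p = 1.05e-06; adjusted p = 0.577 with an estimated correlation). Slc4a1 lost its call in 5 of the 6 fits that left out a library, with adjusted p up to 0.297. The beta-globin gene Hbb-bs, which shares sequence with other globin genes, stood at 376 CPM in WT and 867 CPM in KO. Markers of the ovarian surface and oviduct epithelium were lower as a group, with a median of -0.39. The medians in KO replicates 1 to 3 were -0.15, -0.31 and -0.61, and WT replicate 1 stood at -0.31, so that KO replicate 3 alone lay below each WT library. Of the 14, 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.00025; adjusted p = 0.577 with an estimated correlation).

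For the other cell types, no list passed camera and no member passed over all genes. Endothelial genes had a median of 0.27 (12 tested, camera adjusted p = 0.11), immune cell genes of 0.15 (22, 0.381), smooth muscle and pericyte genes of 0.04 (9, 0.979). Stromal fibroblast genes had a median of -0.10 (11, 0.29) and adipocyte genes of 0.09 (5, 0.29). In these 5 lists 0 members passed adjusted over the list alone. Without KO replicate 3, camera placed the endothelium (2.74e-05), immune cell (0.000201) and smooth muscle (0.0281) lists higher (each 0.491 with an estimated correlation). Without KO replicate 1 it placed stromal fibroblasts lower (0.00766). In the 9 theca and interstitial cell genes the median was -0.08 and the mean 0.14, with camera pointing higher (adjusted p = 0.651), and 3 were higher and 1 was lower adjusted over the list alone. Cyp17a1, the theca cell enzyme of androgen synthesis, stood at 95.6 CPM in WT and 231 CPM in KO (1.27 ± 0.36 SE, adjusted p = 0.432). Sertoli cell markers had a median of -0.15 (8 tested, camera adjusted p = 0.231), with 1 gene lower adjusted over the list alone.

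No gene of the H3K27 methylation machinery, the system that JMJD3 acts in, passed the test. The median was -0.05 with 0 of 13 past the threshold (camera adjusted p = 0.29), and Rbbp7 came nearest at -0.17 ± 0.08 SE (adjusted p = 0.542). The Hox genes, classical targets of this mark, had a median of -0.09 with 0 of 23 past the threshold (camera adjusted p = 0.23). Hoxc8 stood at 20.6 CPM in WT and 15.3 CPM in KO (-0.43 ± 0.12 SE, adjusted p = 0.295). Cell cycle genes were lower by camera (median -0.09, 0 of 36 past the threshold, adjusted p = 0.0131; adjusted p = 0.86 with an estimated correlation). That call ended without WT replicate 1 (0.69), KO replicate 1 (0.287) or KO replicate 2 (0.103), and the median in KO replicate 3 was 0.04. In the cell death and atresia list, 0 of 29 passed, with a median of -0.01, a mean of 0.03 and camera pointing lower (adjusted p = 0.979). The lists of IGF and PI3K signalling (median 0.08, 26 tested, 0.125), extracellular matrix remodelling (0.01, 27 tested, 0.908) and the circadian clock (0.13, 19 tested, 0.257) also had no member past the threshold and no call by camera. In each list of this paragraph 0 members passed adjusted over the list alone.

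Of 23 interferon-stimulated genes, Xaf1 alone passed, over all genes and adjusted over the list alone. The list was higher by camera (median 0.22, adjusted p = 0.000417; adjusted p = 0.618 with an estimated correlation), a call that ended without KO replicate 1 (0.0548). Its medians in KO replicates 1 to 3 were 0.48, 0.14 and -0.06, in the same order as those of the immune cell list (0.54, 0.12 and -0.38) and the endothelium list (0.70, 0.24 and -0.25). Usp18 stood at 2.70 CPM in WT and 3.97 CPM in KO (0.56 ± 0.17 SE, adjusted p = 0.365). Of 18 inflammatory cytokine and chemokine genes none passed over all genes (camera adjusted p = 0.979). Cxcl1 was lower adjusted over the list alone (4.42 against 1.82 CPM, -1.28 ± 0.20 SE, adjusted p = 0.0512 over all genes in edgeR). With an estimated correlation camera called 0 of the 26 lists, against 10 with the preset one, and of the fits that left out a library it was run in that without KO replicate 3 alone. Fry called 0 in one direction and 7 for change in either direction, among them the granulosa, steroidogenesis, theca and interferon lists.

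KO replicate 3 stood apart from the other libraries labelled KO. KO replicates 1 and 2 had the highest correlation of log2 CPM among the 15 pairs of libraries (Pearson r = 0.994), and a chi-square per degree of freedom of 21.1 against 17.0 to 26.3 between WT libraries. The first principal component of log2 CPM, with 33.2% of the variance, set KO replicate 3 at 46.8 and the other libraries between -14.4 and -2.14. The second, with 27.5%, set KO replicates 1 and 2 at -32.7 and -20.4, KO replicate 3 at 6.67 and the WT libraries between 14.3 and 16.7. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom from 17.0 (WT replicates 2 and 3) to 96.8 (KO replicates 1 and 3).

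**Figure D3:**
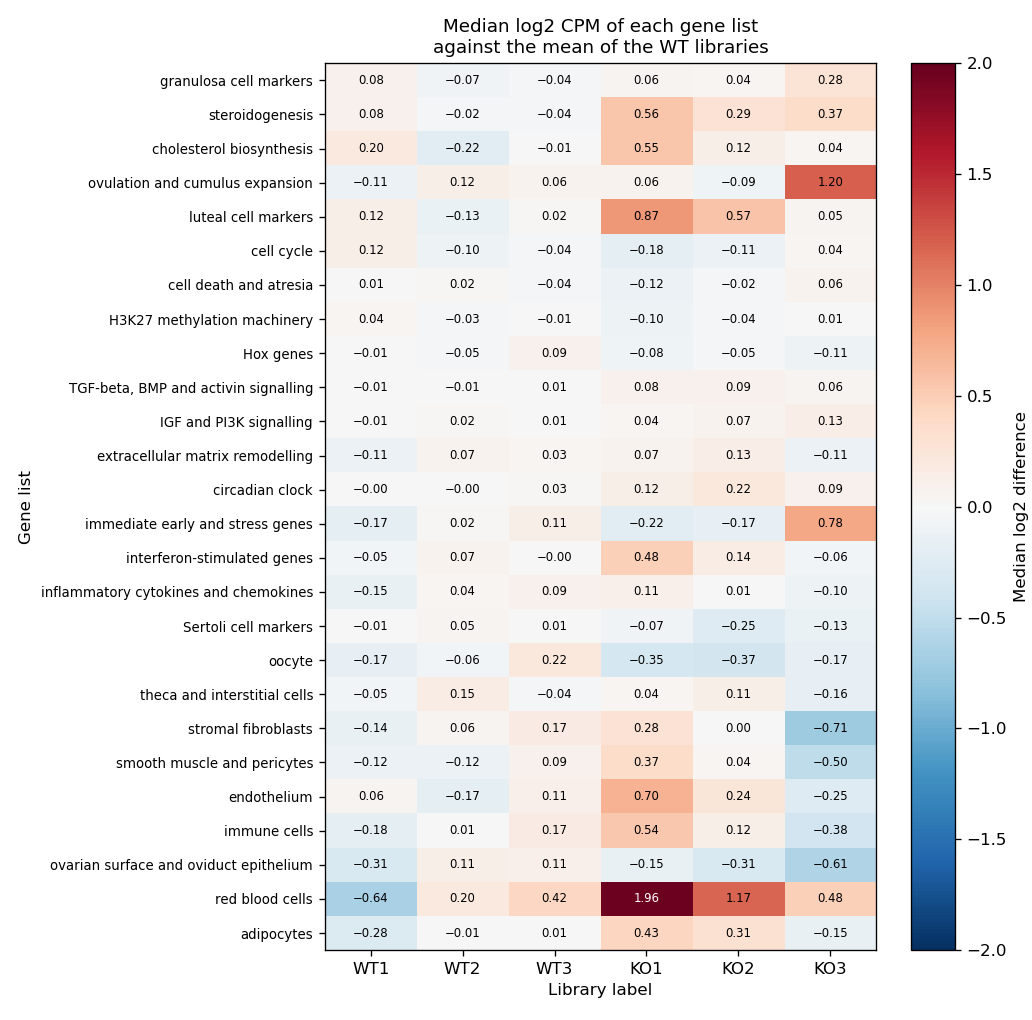
Median log2 CPM of the tested members of each of the 26 gene lists in each library, as the difference from the mean of the WT libraries (red, higher; blue, lower; the number in each cell is the median). KO replicate 3 stands apart in the ovulation list (1.20) and the immediate early list (0.78). The luteal list stands at 0.87, 0.57 and 0.05 in KO replicates 1, 2 and 3, and the red blood cell list at 1.96, 1.17 and 0.48.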

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

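The number of genes called between the libraries labelled KO and WT depended on the processing more than their direction did. Against 23 higher and 17 lower, DESeq2 called 127 and 94, limma-voom with quality weights 37 and 35, no filter 97 and 102, and a filter at a mean of 1 CPM 11 and 10, where fewer genes were tested. RLE and upper-quartile scaling stayed within 1.5 times of these counts, and a minimum absolute log2 fold change of 1 left 16 and 11 by construction. Leaving out 1 library gave between 6 and 324 higher genes and between 2 and 97 lower genes, the upper ends both without KO replicate 3. Of the 40 genes, 8 passed under all 13 alternatives that test genes (Wdfy1, Xaf1, Nnt, Nipal1, mt-Nd3, Gm28438, Gm1821 and Gm42031), 7 passed in only 5, and DESeq2 kept all 40. Kdm6b never passed, and its log2 fold change ran from -0.038 (without KO replicate 3) to 0.40 (without KO replicate 1). Star passed with DESeq2 (adjusted p = 8.32e-07) and limma-voom (0.0152), in a range over alternatives up to 0.662, and Akr1c18 with the same tools (1.57e-06 and 0.00884, up to 0.72). Por passed with DESeq2 (0.0009) and with no filter (7.42e-05), in a range up to 0.467, and Prlr, Fdx1, Srebf2, Cxcl1, Gdf9, Hoxc8 and Aldh1a1 were among the other named genes that gained a call with 1 or more of these alternatives. The list of immediate early and stress genes turned from higher to lower without KO replicate 3 (camera adjusted p = 0.0191, or 0.491 with an estimated correlation), the library in which its median was 0.78. Without 1 library its adjusted p ran from 0.00917 to 0.914. All 10 lists called by camera lost their call with an estimated correlation and by the directional test of fry. With the preset correlation, 5 of them kept it in every fit that left out a library. Keeping it does not by itself show a group difference, since camera called as many lists or more in some other splits, given below. Fry for change in either direction called the steroidogenesis (adjusted p = 0.0183), interferon (0.0183) and red blood cell (0.0353) lists among the 10. That test can pass through few members. In edgeR over all genes, Xaf1 alone passed in the interferon list, Slc4a1 alone in the red blood cell list and none in the steroidogenesis list. The cause of the other differences was not tested.

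The replicate numbers gave no clear sign of pairing. The correlation of same-numbered libraries' deviations from their group means was -0.02, 0.07 and -0.03, and not every library correlated best with its own number. So few pairs cannot exclude a shared litter, day or batch, and the labels do not state a pairing. With the number as a replicate block, 10 genes were higher and 5 lower, 14 of them among the 40. Depth limits what can be seen at low levels: 3 counts correspond to between 0.0584 and 0.0706 CPM, for counting error only.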

Other observations

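The tests of explanations and the counts over other splits in this part were chosen after the results they bear on had been seen, whereas the fit without KO replicate 3 was planned. Without that library, steroid and luteal genes passed singly: Star, Por, Fdx1, Cyp11a1, Fdxr and Srd5a1 were 6 of 19 steroidogenesis genes that rose, with 12 higher adjusted over the list alone (edgeR, Benjamini-Hochberg). Prlr (0.72 ± 0.10 SE, adjusted p = 0.000467), Star, Cyp11a1 and Bhmt rose among the luteal markers, and Dhcr7 and Srebf2 were among the cholesterol genes that rose. Of other groups, Jun fell (-0.61 ± 0.11 SE, adjusted p = 0.00771), Zp3 fell among the oocyte genes, and Cldn5 rose for endothelium and Csf1r for immune cells. The endothelial list was higher (camera adjusted p = 2.74e-05; adjusted p = 0.491 with an estimated correlation). Onecut2, a transcription factor gene chosen after its values were seen, stood at 1.31 to 2.30 CPM in WT, at 24.3 and 16.6 CPM in KO replicates 1 and 2 and at 3.88 CPM in KO replicate 3. The mast cell protease genes Tpsb2 (0.29 to 0.46 CPM in WT, 2.67 and 1.67 CPM in KO replicates 1 and 2, 0.42 CPM in KO replicate 3) and Cma1, chosen in the same way, were also higher in that fit.

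Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave 40 or more genes, and the highest of the others was 0. In 5 of the 10 splits camera called 10 or more lists, as in the real one, and the highest of the others was 15. This was in the 2 splits that put KO replicates 1 and 2 with WT replicate 2 or 3 and KO replicate 3 with the remaining WT libraries. With 10 splits a share under 0.05 cannot be reached. The third split of this kind, with WT replicate 1 beside KO replicates 1 and 2, gave 10 lists, and the split with KO replicates 2 and 3 beside WT replicate 1 gave 12.

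The counts of mt-Nd3 fell while those of Gm28438 rose in each library labelled KO, and the transcripts of the 2 genes differ at 1 of 345 aligned bases. Their summed CPM had a log2 ratio of 0.21 between KO and WT, against -4.97 for mt-Nd3 alone, in line with reads passing between the gene and its nuclear copy. A fall of mitochondrial transcription as a whole is argued against by the 7 other abundant mitochondrial protein-coding genes, whose median log2 fold change was 0.052 (lowest -0.12), although mt-Tg, mt-Tr and mt-Nd4l, which lie beside mt-Nd3 and have under 2 CPM, were also called lower (mt-Nd4l has a nuclear copy too, Gm10222, identical over 294 bases). A base that differs between the mitochondrial genomes of the groups may move these reads, which would make a different strain background a candidate explanation for nuclear genes too, such as Nnt, known to carry a deletion in C57BL/6J, and Wdfy1 and Crb1, known to differ between C57BL/6J and C57BL/6N, although all libraries are labelled C57BL/6J. Within 10 Mb of Kdm6b lay 3 of the 40 called genes, Tvp23b, Tnfsf13os and Xaf1 (0.82 expected, exact one-sided hypergeometric p = 0.048). At 2, 5 and 20 Mb the exact one-sided hypergeometric p ran from 0.0574 to 0.241. Without KO replicate 3 there were 17 of 421 (8.5 expected, exact one-sided hypergeometric p = 0.00552). At the other windows that fit gave an exact one-sided hypergeometric p from 0.00769 to 0.0686. The p was thus under 0.05 at some windows and not at others. These counts bear only on a segment around Kdm6b on chromosome 11. They cannot test a background difference at Nnt (chromosome 13), at Wdfy1 and Crb1 (chromosome 1) or in the mitochondrial genome. Background and the loss of JMJD3 were not told apart for the genes near Kdm6b or for these.

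KO replicate 3 alone held high levels of several ovulation genes (Areg, Ereg, Pgr and, chosen after their values were seen, Ptgs2 at 30.3 CPM and Tnfaip6 at 20.7 CPM). The list median there was 1.20, and 16 of its 20 tested members had a positive fold change between the groups. A library of the WT group under a KO label is argued against: at 15 of the 20 genes with the smallest p without this library, mt-Nd3, Wdfy1 and Amhr2 among them, it lay nearer the other KO libraries than the WT mean, and at Inpp5j, Sec14l1, Kcnab3, Tpsb2 and Gpr176 it lay nearer the WT mean. Cells of the other types that were listed are argued against by their lists. The highest median of these in this library was 0.48, for red blood cells, with the other lists below 0. No list of other cell types was for cumulus cells, so those were not tested for. Handling stress stays open. The immediate early and stress genes had a median of 0.78 in this library, between the values set for and against it. That median cannot tell handling from another inducer of these genes. A wild-type genotype on the background of the KO libraries also stays open, since mt-Nd3, Wdfy1, Nnt and Crb1 may follow background. Kdm6b does not decide it: its 112 CPM in this library lay above the WT libraries (66.2 to 72.8 CPM) and KO replicates 1 and 2. Amhr2 (130 CPM) and Nipal1 (32.6 CPM) lay near KO replicates 1 and 2 (141 and 127 CPM, 32.3 and 33.4 CPM), unlike the genes named above as nearer the WT mean. The stage of the cycle is not in the labels, so no biological explanation was tested, and ovulation in progress in that sample remains a hypothesis that could be checked against the time of collection.

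Amhr2 fell by 1.01 on the log2 scale in the libraries labelled KO. A smaller share of granulosa cells as a whole is argued against by the other 21 granulosa cell markers. Their median log2 fold change was 0.14, with quartiles of -0.03 and 0.31. The lowest was -0.54, of Wt1, the only other marker called. Since Wt1 marks immature granulosa cells, the median cannot test for a smaller share of those cells. The loss of 1 of the 2 Amhr2 copies, as from a recombinase gene placed in that locus, is a candidate explanation: the log2 fold change of -1.01 has an interval that includes the -1 it would give. The labels do not name the recombinase driver, another origin of the same decrease would give the same value, and regulation by JMJD3 stays open.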
